A study of Drosophila melanogaster with 6 samples.

How the data were processed

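RNA was measured in 6 samples of S2, an embryo-derived Drosophila melanogaster cell line with features of blood cells, in 3 groups of 2: control knockdown, NAP-1 knockdown and CBP knockdown. Per the labels' protocols, total RNA was made into libraries with a strand-specific kit that selects messenger RNA, and per the series' design text these were sequenced on a MiSeq. The labels do not say whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

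The authors deposited 1 table of RPKM values, reads per kilobase of feature scaled to the number of reads, together with the number of alignments per sample, a count. The genome build is dm3 per the submitters' processing notes; the aligner, the counting program and their settings are not given in the sources used here. The table has 16384 columns, of which 16381 are features. Of these, 7156 are named by a gene symbol alone, running alphabetically from 128up to NLaz, and 9225 by a RefSeq mRNA and a symbol. Features behave as isoforms, because a symbol-only value is not the total of the mRNAs listed under the same symbol. Whole-gene values are therefore not given for genes listed in part, and genes outside these names were not analysed here. Of 13962 protein-coding genes in a RefSeq gene table for release 6 of the genome, 7812 had a feature in the table and 3799 were analysed.

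Features with a mean of at least 1 RPKM over the 6 samples, 5319 in all, were considered, together with all listed features of Nap1 and nej. Of these 5319, 906 repeated the values of another feature and were left out, as was 1 feature whose name ends in an apostrophe. After the results had been seen, 3 genes whose symbols begin with a number of 3 digits were also left out, because such names could not be told from printed values. They were chosen by name alone, and the calls given for the main comparisons did not change. This gave 4411 features. These were summed per symbol to 3987 genes, 391 of them with more than 1 feature. Transcript lengths, as the median over a gene's transcripts in the BDGP6 annotation, were found for 3937 genes; that build differs from dm3, so only names and lengths were used.

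Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with 1 linear model over all 6 samples, a variance trend with mean expression, and Benjamini-Hochberg adjustment over 3987 genes at a threshold of 0.05. Fold changes are on that log2(RPKM + 1) scale, which understates changes of genes with low values. Count models were not used, since RPKM values are not counts. Gene lists, 41 of them fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where at least 5 members were analysed, and again with the correlation estimated from the data. Camera sets a list against the other genes, so a list that passes need not differ from control. Comparisons that share the control libraries were set against 100 simulations of unchanged groups.

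The genes named were chosen by a rule fixed before the data were examined. It took Nap1 and nej, then for each knockdown the 12 largest rises and 12 largest falls among called genes whose libraries did not overlap between groups. Where fewer than 6 passed in a direction, the list was filled to 6 by the smallest unadjusted p. For NAP-1 against CBP knockdown it took 6 per direction, and for each list up to 4 members with the smallest p, with any member of the chaperone, acetyltransferase, deacetylase and histone lists. Members named beyond these were chosen after their values were seen: CecC, Sod, Klp10A, Cap-G and polo complete counts given for their lists.

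The test was checked on simulated data with the real genes' means and spreads and 200 of 3987 genes changed, 100 of them 2-fold and 100 of them 4-fold. Noise was drawn separately for each gene and library, with equal spread in all groups and no shift shared within a library. The shares recovered and false hold for such data only, and these libraries do share shifts, as with transcript length. The 100 simulations of unchanged groups were drawn in the same way. For NAP-1 knockdown against control, 8.0% of the 2-fold and 79.6% of the 4-fold changes were recovered, with 5.5% of calls false. For CBP knockdown against control these were 6.8%, 78.8% and 6.7%, and for NAP-1 against CBP knockdown 7.8%, 80.0% and 5.3%. In a simulation added after the data were seen, with 10 genes changed between NAP-1 knockdown and control, 0.4% of 5 changes of 2-fold and 12.6% of 5 changes of 4-fold were recovered over 100 simulated sets. Alternatives covered the pseudocount, the minimum mean, the scaling of samples, the samples in the fit, the replicate number, the variance trend, the threshold and each sample left out. Others were added after the data were seen: single features, removal of a loess trend (span 0.5) on transcript length, genes with a symbol-only feature, omission of a pair of libraries, and a list without the gene targeted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.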

Results

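Messenger RNA was profiled in Drosophila S2 cells after knockdown of NAP-1, a histone chaperone that assembles nucleosomes, or of CBP, a histone acetyltransferase encoded by nej, and after a control knockdown. The series' title concerns acetylation of the linker histone H1, and the comparisons address which transcripts differ after loss of either factor. Each group had 2 samples. There were 4838376 and 5188013 alignments in the control samples, 5253846 and 4162019 after NAP-1 knockdown, and 5271196 and 5362319 after CBP knockdown. Across 3987 genes the first principal component held 69.0% of the variance. The control samples had weights of 0.421 and 0.323 on it and the CBP knockdown samples -0.374 and -0.689. NAP-1 knockdown replicate 2 (0.321) lay with the controls, and replicate 1 (-0.002) lay between controls and CBP knockdown.

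Nap1 transcript fell in NAP-1 knockdown. Its listed features summed to 231 ± 16.4 RPKM in the controls (SD, n = 2) and to 23.6 ± 4.2 RPKM after NAP-1 knockdown (SD, n = 2), a log2 fold change of -3.25 ± 0.27 (SE; limma, adjusted p = 0.0296). After CBP knockdown Nap1 stood at 345 ± 28.3 RPKM, which did not pass the test against control (adjusted p = 0.148). The call for Nap1 was lost on omission of any 1 of the 6 libraries, with adjusted p between 0.0817 and 0.431, while its fold stayed between -3.43 and -3.08. It was also lost with median-of-ratios scaling, 4 samples in the fit and single features (adjusted p = 0.113, 0.322 and 0.0647). The nej transcript was low in all groups, with 3 listed isoforms. It stood at 3.25 and 2.47 RPKM in the controls, 1.26 and 2.41 RPKM after NAP-1 knockdown, and 0.899 and 0.363 RPKM after CBP knockdown. Against control the fold for nej was -1.26 ± 0.37 (SE, adjusted p = 0.0466) in CBP knockdown. That call was lost without either control sample or either CBP knockdown sample (adjusted p between 0.068 and 0.228), and with a pseudocount of 0.1, median-of-ratios scaling, quantile normalization and single features (adjusted p = 0.0596, 0.0529, 0.222 and 0.0761). With the trend on transcript length removed it was 0.17 (adjusted p = 0.687), so on the log2(RPKM + 1) scale the fall of nej did not exceed the fitted trend. That scale understates changes at such low values. At a pseudocount of 0.1 the fold for nej was -2.11, and the trend was not removed there.

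**Figure D1:**
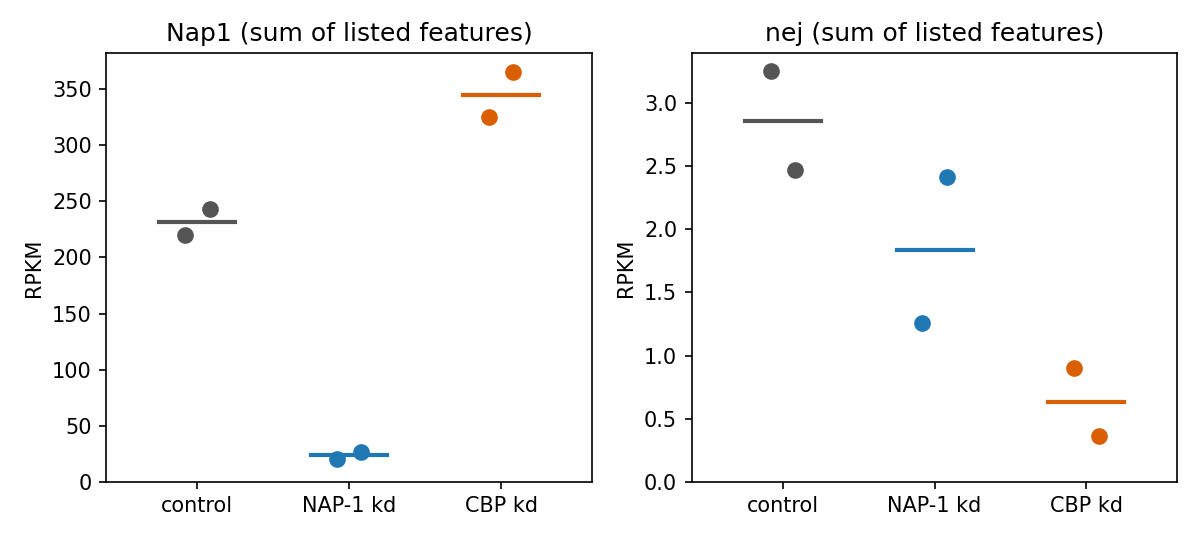
RPKM (vertical axis, from 0) of Nap1 and nej, summed over listed features, in the 3 groups; points are samples (n = 2 per group) and bars are group means. Nap1 lies at 20.6 and 26.5 RPKM after NAP-1 knockdown against 220 and 243 RPKM in the controls, and nej at 0.899 and 0.363 RPKM after CBP knockdown against 3.25 and 2.47 RPKM.

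The comparison of NAP-1 knockdown with control asked which transcripts depend on this chaperone. Of 3987 genes, 0 were higher and 1 was lower, Nap1 itself (limma, adjusted p under 0.05). At an unadjusted p under 0.05, 39 genes were higher and 101 were lower. The next genes by unadjusted p did not pass the adjustment. Among those with higher values, CG43236 had 3.12 and 3.91 RPKM after NAP-1 knockdown against 0.000 and 0.000048 RPKM, with an adjusted p of 0.764. Acyp2, an acylphosphatase gene, had 2.59 and 3.27 RPKM against 0.109 and 0.104 RPKM. Qtzl had 5.86 and 8.21 RPKM against 0.798 and 1.48 RPKM, and CG11329, CG3793 and CG15766 had log2 differences of 2.28, 2.11 and 1.36. Among those with lower values, msps, which encodes a microtubule polymerase, had 3.36 and 3.94 RPKM against 14.9 and 10.5 RPKM. Tbc1d15-17 had 0.415 and 0.394 RPKM against 5.36 and 6.66 RPKM, and Neos, CG2225 and CycG had log2 differences of -1.48, -1.67 and -1.59. In simulated data with 10 changed genes, 12.6% of 4-fold and 0.4% of 2-fold changes were recovered, and with 200 changed genes 79.6% and 8.0%. If few genes changed, most changes of 4-fold or less were therefore not detectable.

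Of the gene lists, 4 passed in NAP-1 knockdown (camera, preset correlation), and 0 did so with an estimated correlation, where the adjusted p was 0.718 for each of the 4. The NAP family and histone chaperone list was lower (adjusted p = 0.0118), with 1 of 13 members called over all genes and 2 called when adjusted over the list alone. Without Nap1, the gene targeted, that list had an adjusted p of 0.0743 and a median log2 fold change of -0.25. Histone acetyltransferases were lower as a list (adjusted p = 0.0378), with 0 of 10 members called. Of these, Tip60 stood at 3.87 and 3.9 RPKM after NAP-1 knockdown against 7.31 and 7.49 RPKM. Oxidative phosphorylation genes (adjusted p = 0.0378, 0 of 52 called) and cytosolic ribosomal proteins (adjusted p = 0.0422, 0 of 25 called) were higher as lists, the latter with a median of 0.07 but a mean of -0.01. The camera calls of these last 3 lists were lost with the length trend removed (adjusted p = 0.496, 0.928 and 0.613). Without NAP-1 knockdown replicate 1 or without control replicate 2, 0 lists passed, and without control replicate 1 only 1 did.

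Many more transcripts differed in CBP knockdown: 339 genes were higher and 693 lower than in control (limma, adjusted p under 0.05). Of those lower, 315 were in the longest of 5 length bins, 107 of them still called with the length trend removed. The libraries differed in make-up too: 4743 and 4059 features reached 1 RPKM in CBP knockdown against 5722 and 5371 in the controls. The 20 most abundant genes held 32.9% and 37.74% of summed RPKM against 22.24% and 27.24%. CBP loss and library quality were not told apart. Of all calls, 67.2% were lower. The share lower was 56.4% with median-of-ratios scaling and 52.7% with quantile normalization, which shifted the median log2 fold change of all genes from -0.15 by 0.16 and 0.27. TotM, which encodes a secreted stress-response peptide, showed the largest rise, 6.10 ± 1.70 (SE, adjusted p = 0.0421), from 0.571 and 0.0041 RPKM to 59.4 and 122 RPKM. Its call was lost with the length trend removed (adjusted p = 0.069). It stood at 69.3 RPKM in NAP-1 knockdown replicate 1 and at 0.00153 RPKM in replicate 2. CG42792 rose by 4.57 on the log2 scale, CG43210 by 3.82, CG42259 by 3.81, CG44475 by 3.37, CG7280 by 3.18 and CG11655 by 3.11. The rises of CG14818, CG16713, CG15739, CR41620 and CG4586 lay between 2.71 and 3.09. ImpL2, which encodes a secreted antagonist of insulin signalling, fell by 5.31 ± 0.57 (SE), from 376 and 232 RPKM to 11.6 and 3.45 RPKM. The transcripts of lolal, mod, a nucleolar protein gene, and Hrb27C, an RNA-binding protein gene, had log2 fold changes of -4.86, -4.30 and -4.23. Falls for CG3800, CG7564, the kinase gene hipk, CG12360, the calmodulin gene Cam, Aps, R and CG8188 were -4.20, -4.14, -4.14, -4.13, -3.94, -3.89, -3.88 and -3.85. No call was made, higher or lower, without control replicate 1 or without CBP knockdown replicate 2 (0 genes in each), and 31 were higher and 177 lower without control replicate 2. Without CBP knockdown replicate 1 the numbers were 109 and 592, and without NAP-1 knockdown replicate 1 or 2 they were 520 and 734 or 541 and 737. At a mean of at least 5 RPKM 311 were lower, with quantile normalization 413 were lower, and with 4 samples in the fit 550 were higher.

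Antimicrobial peptides, the effectors of the fly's humoral immune response, rose as a group in CBP knockdown. Of 10 measured, 5 were higher and 0 lower (camera adjusted p = 0.0105; adjusted p = 0.596 with an estimated correlation), and 6 were higher when adjusted over the list alone. DptB went from 13.2 and 7.8 RPKM to 55.6 and 53.9 RPKM, and CecA1 from 16.2 and 19.7 RPKM to 43.9 and 42.6 RPKM. Mtk and CecC rose by 1.63 and 1.66, and AttA was the other. The attacin and cecropin genes are near-identical families, so reads may be divided uncertainly among them. Members of this list are short, with a median of 387 nt, and with the length trend removed the adjusted p was 0.15 and 2 members were called. At a mean of at least 5 RPKM the adjusted p was 0.0589.

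Of 15 oxidative stress and glutathione genes, 4 were higher and 1 lower (camera adjusted p = 0.0341; adjusted p = 0.596 with an estimated correlation), and 6 were higher and 1 lower when adjusted over the list alone. The glutathione S-transferase genes GstD1, GstD2 and GstE3 rose by 1.81, 2.48 and 1.55 and the superoxide dismutase gene Sod by 1.32, while the peroxiredoxin gene Jafrac1 fell by 2.04. With the length trend removed GstD1, GstD2 and Jafrac1 kept their calls and GstE3 did not (1.12, limma adjusted p = 0.0655). Sod had no transcript length and was not adjusted. Of 52 oxidative phosphorylation genes, 6 were higher and 1 lower (camera adjusted p = 0.0244; adjusted p = 0.596 with an estimated correlation), and 0 were called when adjusted over the list alone. CG7630, CG4692 and CG12859 rose by 1.31, 1.32 and 1.31, and CG7580 fell by 1.53. With the length trend removed the 6 higher genes all lost their call (limma, adjusted p between 0.0718 and 0.16). CG7580 kept its call (-2.02, adjusted p = 0.0304). The calls of these lists were lost with quantile normalization (adjusted p = 0.122 and 0.109), at a mean of at least 5 RPKM (adjusted p = 0.274 and 0.198) and with the length trend removed (adjusted p = 0.195 and 0.496). That of the stress list was lost too without NAP-1 knockdown replicate 1 or 2 (adjusted p = 0.054 and 0.0522) or CBP knockdown replicate 2 (adjusted p = 0.0621).

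Mitosis genes fell as a group: of 12 measured, 7 were lower and 0 higher (camera adjusted p = 0.0341; adjusted p = 0.596 with an estimated correlation), the same numbers as when adjusted over the list alone. The spindle checkpoint kinase gene BubR1 went from 6.55 and 3.69 RPKM to 0.385 and 0.172 RPKM, and the kinesin genes Klp61F and Klp10A had log2 fold changes of -2.62 and -1.66. CycA, sti, Cap-G and polo were the others. With the length trend removed BubR1, Klp61F and CycA kept their calls, and Klp10A, sti, Cap-G and polo lost theirs. Extracellular matrix genes were lower at 4 of 7, with 0 higher (camera adjusted p = 0.0341; adjusted p = 0.596 with an estimated correlation), and 5 were lower when adjusted over the list alone. Glt, the laminin subunit genes LanA and LanB1, and the collagen gene vkg had log2 fold changes of -3.37, -3.49, -2.46 and -1.12. With the length trend removed Glt, LanA and LanB1 kept their calls and vkg did not (-0.06, limma adjusted p = 0.881). Members of these lists are long, with median lengths of 2704 nt and 6091 nt, and with the length trend removed the adjusted p was 0.15 for mitosis and 0.481 for the matrix. Without NAP-1 knockdown replicate 1 or 2 it was 0.0549 and 0.0554 for mitosis and 0.054 and 0.0522 for the matrix, and without CBP knockdown replicate 1 it was 0.0539 for the matrix. At a mean of at least 5 RPKM it was 0.198 for mitosis.

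**Figure D2:**
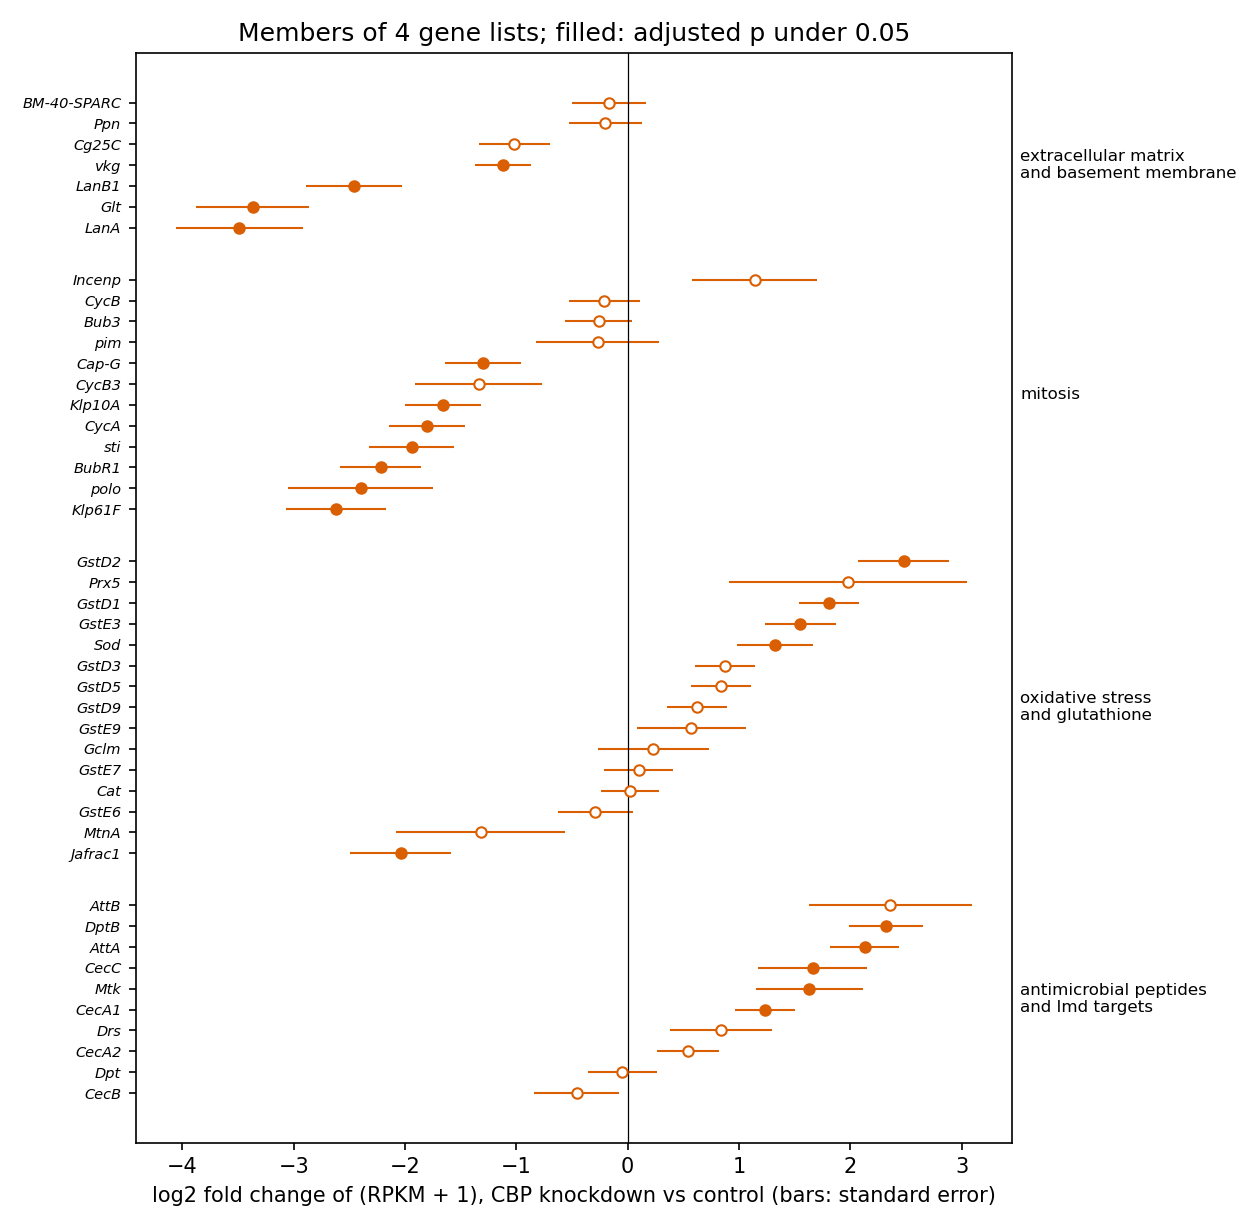
Log2 fold change of RPKM + 1 in CBP knockdown against control (horizontal axis) for members of 4 gene lists; points are genes, bars are standard errors, and filled points have an adjusted p under 0.05. Of 10 antimicrobial peptide genes 5 are higher, and of 12 mitosis genes 7 are lower.

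Among chromatin genes, 5 of 13 NAP family and histone chaperone members were lower in CBP knockdown and 1 was higher, although the list did not pass (camera adjusted p = 0.0898). The remodelling ATPase gene Iswi (-2.78), Acf1, which encodes its partner (-1.88), and Caf1, which encodes a chromatin assembly factor subunit (-1.39), were among those lower. Hira, the gene of a chaperone for the replacement histone H3.3, rose by 1.31. Of 10 acetyltransferase list members 3 were lower, nej, Nipped-A (-2.38) and chm (-1.53). Of 5 deacetylase list members 1 was lower, Sin3A (-1.70), and of 4 histone genes 1 was lower, His2Av (-1.12). With the length trend removed 6 chaperone list members were lower and 1 higher, 0 acetyltransferase list members were called, and of the deacetylase list 0 were lower and 1 was higher. Acf1 lost its call (-0.99, limma adjusted p = 0.0658), so the 6 include members not called before. Caf1 had no transcript length and was not adjusted.

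Fold changes depended on transcript length. In CBP knockdown the median log2 fold change was 0.29 in the shortest of 5 equal bins of genes, of 116 to 967 nt, and -1.07 in the longest, of 2900 nt or more. Across 3937 genes, which are not independent replicates, Spearman's rho with length was -0.38 for CBP knockdown, -0.37 for NAP-1 knockdown and -0.24 for control replicate 2 against replicate 1. Of the genes called lower in CBP knockdown, 315 were in the longest bin, of which 107 were still called lower with the trend removed, and 33 were in the shortest.

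**Figure D3:**
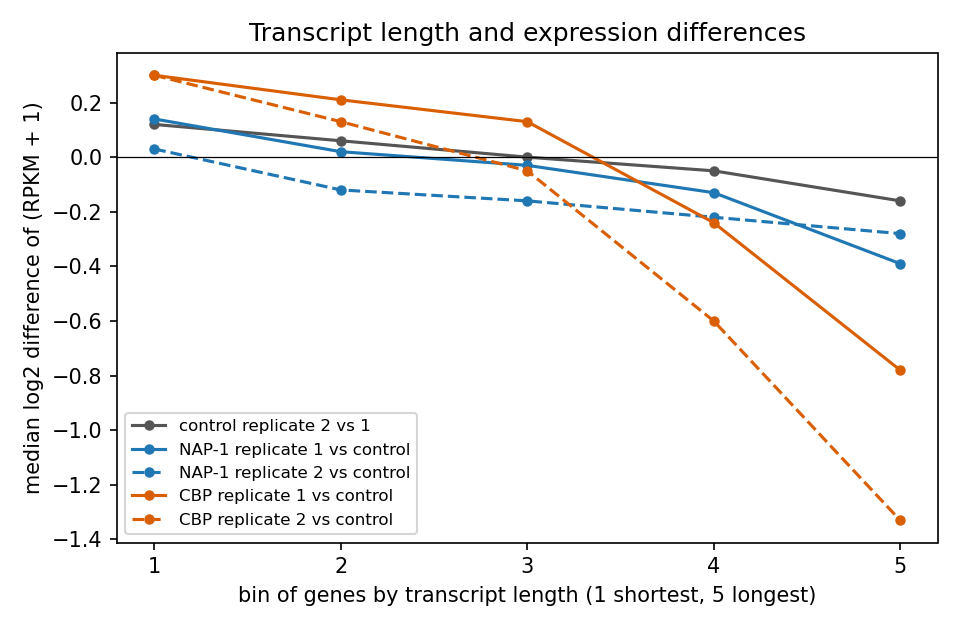
Median log2 difference of RPKM + 1 (vertical axis) in 5 equal bins of genes by transcript length (horizontal axis), for single knockdown libraries against the mean of the controls and for control replicate 2 against 1. In the longest bin the medians are -1.33 and -0.78 for CBP knockdown replicates 2 and 1, and -0.16 between the controls.

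NAP-1 and CBP knockdown were also compared with each other. After NAP-1 knockdown 57 genes were higher and 66 lower than after CBP knockdown (limma, adjusted p under 0.05). ImpL2, at 94.1 and 182 RPKM against 11.6 and 3.45 RPKM, was higher by 4.14, Yeti by 3.27, the fatty acid synthase gene CG3523 by 3.26, CG3107 by 3.22 and CG17454 by 3.18, and CG7564 was higher too. Lower were Nap1 (-3.83), CG44475 (-3.59), CG42792 (-3.31), CG42259 (-2.93), CG4586 (-2.91) and CG11655 (-2.77). The numbers were 1 and 1 at a pseudocount of 0.1, 0 and 2 for single features, 0 and 1 with 4 samples in the fit, 128 and 107 with median-of-ratios scaling, 31 and 52 with the length trend removed, and 108 and 97 for symbol-only genes. Without NAP-1 knockdown replicate 1 they were 163 and 295, and without any other single library at most 1 gene was called.

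Across genes, the log2 fold changes of NAP-1 and CBP knockdown had a Pearson correlation of 0.63 and a Spearman correlation of 0.66. Simulations against the same controls in which neither knockdown changed any gene gave a Pearson correlation of 0.5. That value is no chance level for 0.63, since the real fold changes of CBP knockdown had an SD of 1.14 across genes. Such changes lower the correlation that shared controls alone would give. The covariance was 0.328 against a simulated 0.09, a difference of 0.238. With the knockdowns set against different control samples the correlation was 0.41 or 0.38, so part of the correlation of 0.63 may come from the shared controls. NAP-1 knockdown replicate 1 alone had a correlation of 0.7 with CBP knockdown and replicate 2 alone 0.2. A single unchanged library simulated against the same controls gave 0.41, with CBP knockdown simulated as unchanged too. For the same reason 0.41 is no chance level for either replicate. Set against different controls, replicate 1 had 0.62 or 0.43 and replicate 2 had 0.07 or 0.06. An overlap of calls could not be judged, since the 1 gene called in NAP-1 knockdown was Nap1, the gene targeted.

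**Figure D4:**
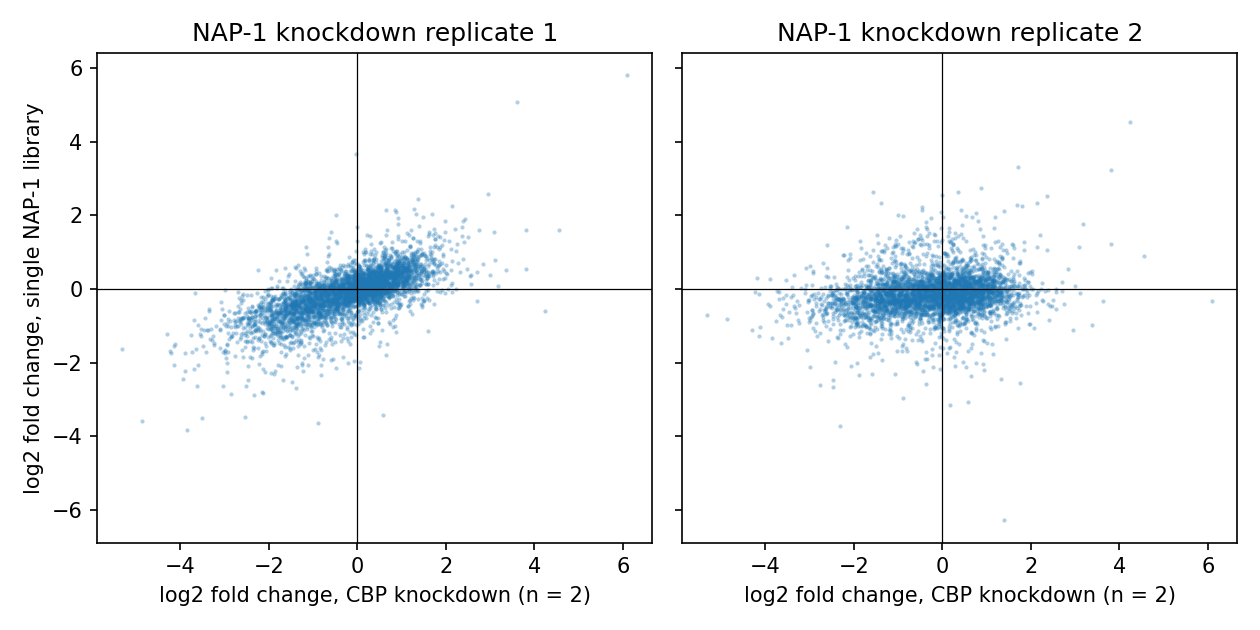
Log2 fold change of RPKM + 1 against the mean of the controls in each NAP-1 knockdown library (vertical axis) and in CBP knockdown (horizontal axis, n = 2); points are 3987 genes. The correlation across genes is 0.7 for replicate 1 and 0.2 for replicate 2. The simulated 0.41 for an unchanged library held CBP knockdown unchanged too, so it is no chance level for either.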

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

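The single features, the length trend, the genes with a symbol-only feature and the omission of a pair of libraries were chosen after the data were seen. A planned fit with no minimum RPKM was not run, since features below a mean of 1 RPKM were not mapped. Of 249 values over the 13 results of the comparisons, 143 stayed within their bound, 84 moved further, 21 lost their call and 1 reversed. The bound was the same side of the threshold for a gene and 1.5 times for a count. For a correlation it was the SD of the correlations between single NAP-1 and CBP knockdown libraries. By that rule 0.41 and 0.38 counted as unmoved from 0.63. For named genes in CBP knockdown, 303 of 392 kept their call and 89 lost it, and in NAP-1 against CBP knockdown 82 of 182 kept it and 100 lost it, with no change of direction; for lists, 88 of 149 kept it and 61 lost it. The cause was not tested except where stated.

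Nap1 in NAP-1 knockdown lost its call at a nearly unmoved fold with median-of-ratios scaling (-3.14, adjusted p = 0.113), 4 samples in the fit (-3.25, adjusted p = 0.322), single features (-3.24, adjusted p = 0.0647) and without a pair of libraries, NAP-1 knockdown replicate 1 and CBP knockdown replicate 2 (-3.08, adjusted p = 0.629); fewer samples leave fewer degrees of freedom. Its adjusted p ranged from 0.0239 to 0.629. Nej in CBP knockdown lost its call at a pseudocount of 0.1 (-2.11), with median-of-ratios scaling (-1.14), quantile normalization (-0.56), single features (-1.14) and without that pair (-1.02), and reversed to 0.17 with the length trend removed. Its adjusted p ranged from 0.0407 to 0.687, and was 0.209 or 0.122 without control replicate 1 or 2 and 0.068 or 0.228 without CBP knockdown replicate 1 or 2.

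Genes lower in NAP-1 knockdown numbered 0 with median-of-ratios scaling, 4 samples, single features, symbol-only genes (which leave out Nap1) and without that pair. With a 2-fold change and no overlap in place of a test, 30 were higher and 113 lower, and 88 genes were lower and 16 higher in both knockdowns; chance separates 33.3% of genes at 2 samples against 2. In CBP knockdown 311 genes were lower at a mean of at least 5 RPKM, where fewer genes were tested, 413 with quantile normalization, and 0 were higher or lower without that pair; 550 were higher with 4 samples and 606 at an adjusted p under 0.1.

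NAP-1 against CBP knockdown gave 1 higher and 1 lower at a pseudocount of 0.1, 128 and 107 with median-of-ratios scaling, 0 and 1 with 4 samples, 415 and 299 at an adjusted p under 0.1, 653 and 341 by 2-fold change, 0 and 2 for single features, and 0 and 0 without that pair. The number higher was 31 with the length trend removed and 108 for symbol-only genes. The correlation of fold changes was 0.2 without that pair, and 0.41 or 0.38 with NAP-1 and CBP knockdown set against different controls.

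Lists passing in NAP-1 knockdown numbered 1 at a pseudocount of 0.1, with median-of-ratios scaling, quantile normalization, the length trend removed and symbol-only genes, 7 at an adjusted p under 0.1, and 0 without that pair or with an estimated correlation. In CBP knockdown they numbered 0 at a mean of at least 5 RPKM, with the length trend removed and with an estimated correlation, 2 with 4 samples, 15 at an adjusted p under 0.1 and 3 without that pair.

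Leaving out each sample in turn leaves a group with 1 sample, which is assumed to vary like the others. It moved Nap1 between -3.43 and -3.08, nej between -1.50 and -1.02, and the correlation between 0.2 and 0.7. The gene called lower in NAP-1 knockdown without control replicate 2 was not Nap1, and was also the gene lower in both knockdowns. In CBP knockdown the number higher ranged from 0 to 541 and lower from 0 to 737. For NAP-1 against CBP knockdown these ranged from 0 to 163 and from 0 to 295. Lists ranged from 0 to 6 in NAP-1 knockdown and from 2 to 6 in CBP knockdown.

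Replicate numbers recur across groups but were not taken to pair the samples, since no label says what they share and 2 pairs are too few to judge. Deviations of samples with the same number correlated at 0.24 for control and NAP-1, 0.13 for control and CBP, and -0.24 for NAP-1 and CBP knockdown. With the replicate number as a block, 0 genes were lower in NAP-1 knockdown (Nap1 -3.25, adjusted p = 0.149), 190 were higher and 505 lower in CBP knockdown (nej -1.26, adjusted p = 0.0691), 0 and 0 differed between the knockdowns, and 1 list passed in NAP-1 knockdown.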

Other observations

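Several gene lists did not pass as lists in CBP knockdown, yet held called members. Of 7 RNA interference genes 3 were lower: AGO2, which encodes the effector of small interfering RNAs, fell by 3.34, AGO1 (-1.74) and Dcr-1 (-1.54) being the others (list adjusted p = 0.126). Of 5 immediate early genes 3 were lower, cbt (-2.94), h (-2.01) and the Fos gene kay (-1.83), with a list adjusted p of 0.0797. Of 10 lipid genes 3 were lower, the fatty acid synthase gene CG3523 (-3.66), Acsl (-3.01) and Lpin (-0.99), with a list adjusted p of 0.0898. Of 11 endoplasmic reticulum stress genes 4 were lower, Ire1, Hsc70-3, Cnx99A and Ero1L, with log2 fold changes of -1.47, -2.40, -1.46 and -1.32. Members of the RNA interference and lipid lists are long, with median lengths of 4145 nt and 3687 nt, against 2237 nt and 2219 nt for the other lists. With the trend on transcript length removed, AGO2, cbt, h, CG3523, Acsl and Ero1L were still called, and AGO1, Dcr-1, kay, Lpin, Ire1, Hsc70-3 and Cnx99A were not.

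Glycolytic genes went both ways in CBP knockdown. Gapdh2 rose by 1.29 while the lactate dehydrogenase gene ImpL3 fell by 1.74 and the hexokinase gene Hex-A by 2.60. In the amino acid biosynthesis list CG3011, a serine hydroxymethyltransferase gene, rose by 2.38, from 74.4 and 66.5 RPKM to 331 and 415 RPKM. The apoptosis genes Dredd and p53 rose by 1.19 and 0.93, the call of p53 being lost with the length trend removed (adjusted p = 0.0738).

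Plasmatocyte and phagocytosis genes, of the blood cell type that S2 cells resemble, had 2 of 5 members lower in CBP knockdown, ush (-1.92) and Pvr (-1.47), and 5 lower when adjusted over the list alone. The list did not pass (camera adjusted p = 0.0681), its members have a median length of 4654 nt, and 0 were called with the length trend removed. Marker lists of other cell types held 0 to 3 analysed genes each. The neuronal gene Snap25 (-1.39), the fat body and gut gene LM408 (-1.41) and 1 of 3 muscle genes, sls (-1.40), were lower, with a median of -0.07 over the muscle list. With the length trend removed Snap25 was still called, and sls (0.45) and LM408 (-0.84) were not. Of the germline (2 genes), ovarian somatic (1 gene) and crystal cell (1 gene) lists, 0 members were called over all genes, and armi (-1.07) and msn (-1.02) were lower when adjusted over the list alone, each being its list's single gene.

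The tests of loss of Nap1 alone, of the spread of the median share and of 1 factor per library were chosen only after the result was seen. NAP-1 knockdown replicate 1 lay toward the CBP knockdown libraries. If CBP knockdown reads had been mixed into it, its Nap1 level would allow a share of at most 5.96%. The median share needed at 1032 genes called in CBP knockdown was 25.4% with NAP-1 knockdown replicate 2 as the baseline, and 43.1% with the controls. These genes were called against the same controls, so noise in the controls may raise the share of 43.1%. The bound set in advance was not met, since the lower quartile over genes was 2.09%. The median's own bootstrap interval over 1000 draws began at 23.4%, but it treats genes as independent and holds no spread between libraries. Whether a mixture is the whole of it was therefore not decided. A length trend as the whole cause is argued against, since the correlation of replicate 1 with CBP knockdown was 0.67 with the trend removed. Loss of Nap1 transcript alone is argued against too. Replicate 2, with a Nap1 level 1.29 times that of replicate 1, correlated with CBP knockdown at 0.07 or 0.06 against different controls. A difference in the state of the culture or in its handling may remain as an explanation and was not tested.

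Long transcripts were lower in CBP knockdown. Of 693 genes called lower, 422 (60.9%) were still called with the length trend removed, above the 50% set in advance. That share overstates the case, since removal lowers the fold changes of shorter genes, whose lower calls could hardly be lost. Of 5 equal bins from the shortest, bins 1, 2 and 3 kept 33 of 33, 63 of 63 and 89 of 96. Genes without a length were not adjusted. Bins 4 and 5 kept 120 of 175 and 107 of 315. Those kept in bins 4 and 5 argue against the trend as the source of all lower calls. This leaves open what lowers long transcripts. Rescaling without 33 abundant and ribosomal protein genes decides nothing, as it applies 1 factor per library and left the longest bin at -1.10. One factor for every gene of a library, as when a few abundant genes take more of the reads, is argued against as the whole of it, since for each CBP knockdown library against each control the shortest bin lay above 0 and the longest below, at least 0.96 apart, against 0.28 between the controls. RNA integrity and an effect of CBP loss on long genes may each give such a trend, and neither was tested.

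Control replicates differed at least 2-fold at 312 genes. Division of reads among isoforms is a candidate explanation: such genes were 1.91, 3.09 and 5.08 times as frequent among genes with several RefSeq mRNAs as among genes with 1, in 3 bins of expression from lowest to highest. The split did not use which isoforms were listed, so it does not bear on listing in part. Transcript length was not held fixed. RefSeq mRNA numbers were found for 98.6% of genes. No biological explanation was tested for this pattern.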
